A study of Mus musculus with 24 samples.

How the data were processed

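RNA sequencing of total RNA was analysed for 24 libraries of mouse bone marrow-derived macrophages (C57BL/6J, age 12 weeks). The libraries form 6 groups of 4: wild-type (WT) and OGT knockout (KO) cells, each unstimulated (M0), given LPS at 100 ng/ml for 12 hours, or given IL-4 at 10 ng/ml for 12 hours. Libraries are named by group and by the number in their label code, which runs from 1 to 4 in WT and from 5 to 8 in KO. The labels do not say whether libraries of a group come from separate animals or separate cultures, so the p-values measure the spread between these libraries.

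The deposited values are raw counts of reads per gene symbol, not normalised. Per the submitters' processing notes, reads were aligned with TopHat2 2.1.0 to the mouse genome mm10 (GRCm38) and the deposited counts were made with HTSeq 0.9.1. The gene annotation, the library kit and the strand setting are not given in the sources used here, so reads from overlapping or antisense genes cannot be told apart. Each library holds 24421 gene symbols and 5 summary lines, and the summary lines were left out of all totals. Gene positions come from the RefSeq table of GRCm38.p6, in which 23204 symbols matched directly and 24313 matched when synonyms were included.

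Each library total is the sum of its gene counts. It ranged from 63429271 to 94942464 in 21 libraries and from 172771 to 209368 in 3 LPS libraries. Counts per 1e6 counts (CPM) were computed with edgeR's effective library sizes. A count of 0 allows up to 3 counts, or 0.0303 to 0.055 CPM in the 21 deep libraries and 15.5 to 17.9 CPM in the shallow ones. These limits cover counting error only.

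Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM factors, the filterByExpr filter by group (14693 genes kept), and the quasi-likelihood test. All 24 libraries entered a single fit with 1 coefficient per group and 18 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the 14693 genes. The 9 contrasts were KO against WT in each of the 3 states, LPS and IL-4 against M0 in each genotype, and both genotype by stimulation interactions. An interaction is the response of KO minus the response of WT. Errors of log2 fold changes are standard errors (SE), and errors of CPM are standard deviations (SD).

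The samples in each fit, the tests, the gene lists, the rule for naming genes and a set of alternatives were fixed before the data were examined. The rule names Ogt first and Oga (Mgea5 in the files), Rps6kb1 and Lyz2 whatever their test. It adds the 8 called genes with the largest change in each direction for KO against WT and for the interactions, and 6 for the stimulations, with a mean of at least 5 CPM in the higher group. For KO against WT the 4 values of each genotype must also not overlap. For each list, up to 4 members with the smallest adjusted p are named, as are Nos2, Il6, Il1b, Tnf, Il12b, Cxcl10, Arg1, Retnla, Chil3 and Mrc1 in the stimulation contrasts.

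Of 35 lists, 22 hold pathways: O-GlcNAc cycling and the hexosamine pathway; proinflammatory cytokines and chemokines; M1 markers and effectors; NF-kB feedback genes; interferon-stimulated genes; IL-4 (M2) markers; the amino acid response (ATF4 targets); ER chaperones and the unfolded protein response; heat shock proteins; glycolysis and hypoxia response; oxidative phosphorylation and the TCA cycle; cholesterol biosynthesis (SREBP2 targets); LXR targets and fatty acid synthesis; insulin and mTOR signalling; mitosis and DNA replication; p53 targets; NRF2 targets; lysosome and autophagy; MHC class II presentation; ribosome biogenesis; cytosolic ribosomal proteins; and macrophage identity. The other 13 hold markers of neutrophils and their precursors, T and NK cells, B cells, dendritic cells, mast cells and basophils, erythroid cells, megakaryocytes, stromal cells, endothelial cells and osteoclasts, sex-linked genes, mitochondrially encoded transcripts, and small structural RNAs. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and fry were run beside it. Fry asks whether a list's genes move, on balance, in a single direction. Members were also counted after adjustment over the list alone.

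The procedure was tested on simulated counts, with changed genes added. The means were those of the WT M0 libraries for all 6 groups, with the library sizes and the spread per gene estimated from all libraries. Counts were drawn independently with no effect of the label number, so the rates of false calls do not cover such an effect. For KO against WT in M0 (14217 genes) the procedure recovered 85.1% of genes changed 1.5-fold, and 100% of those changed 2-fold and 4-fold, with 11 false calls (5.47% of calls). For KO against WT in LPS (14209 genes) it recovered 82.1%, 94% and 100%, with 19 false calls (9.36%). For LPS against M0 in WT (14218 genes) it recovered 79.1%, 97% and 100%, with 6 false calls (3.16%). For the LPS interaction (14215 genes) it recovered 64.2%, 86.6% and 100%, with 17 false calls (9.24%).

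Genotypes share no label number, so KO against WT has no block. Within a genotype the numbers recur across states. Over 8928 genes, deviations from the group means of KO libraries with the same number in M0 and IL-4 correlated at 0.36 to 0.6 in each of 4 pairs. Each lies over the limit of 0.1, so from the data, not from the labels, these numbers pair the libraries of that contrast. A fit with the number as a block was an alternative.

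That set held DESeq2 1.42.0 with its own size factors, edgeR's RLE factors, no low-count filter, a fit on only the groups compared, the replicate block, and leaving out each library in turn. Alternatives chosen after the data were seen left out the 3 shallow libraries, KO numbers 5 and 6, or KO numbers 7 and 8, or summed the counts of number pairs (1 with 2, 3 with 4, 5 with 6, 7 with 8). An effect of the number within a genotype was tested with an edgeR F test on the number, adjusted for state, and its genes were counted in windows of 10 Mb. The number of genes whose 4 values in a genotype lie beyond all 4 of the other was counted, and chance gives a share of 2.86%.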

Results

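Ogt encodes the enzyme that attaches O-linked N-acetylglucosamine to nuclear and cytosolic proteins, and the comparisons ask how OGT knockout (KO) mouse macrophages differ from wild-type (WT) cells at rest (M0) and after 12 hours of LPS or IL-4. Each group holds 4 libraries. Gene counts per library ranged from 63429271 to 94942464 in 21 libraries. WT LPS libraries 1 and 2 held 209368 and 201097 and KO LPS library 7 held 172771. In these 3 shallow libraries between 10042 and 10203 genes had a count, against 15958 to 16517 in the deep ones. The median deep library was 368 times as deep as the median shallow one.

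**Figure D1:**
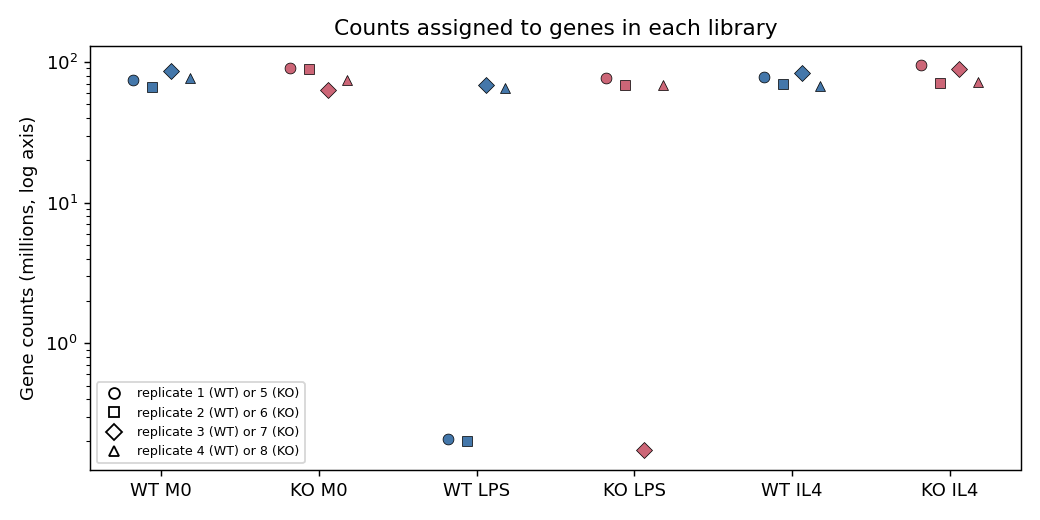
Gene counts per library (log axis) for the 6 groups, with 1 marker per library. WT LPS libraries 1 and 2 (209368 and 201097) and KO LPS library 7 (172771) lie far under the other 21 libraries (63429271 to 94942464).

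Ogt mRNA was lower in KO than in WT macrophage cultures in all 3 states, by less than a factor of 2. Its mean fell from 49.6 ± 2.64 to 35.4 ± 1.13 CPM in M0 (SD, n = 4), from 59.2 ± 5.93 to 40.6 ± 8.91 CPM in LPS and from 54.4 ± 4.05 to 33.3 ± 1.24 CPM in IL-4. The log2 fold changes were -0.49 ± 0.057 (SE, adjusted p = 1.01e-06), -0.63 ± 0.072 (4.22e-07) and -0.71 ± 0.057 (2.82e-09). Every KO library lay under every WT library of its state. Ogt stood at 34.5, 34.6, 36.9 and 35.8 CPM in KO M0 against 47.3 to 52.4 CPM in WT M0. After LPS it stood at 34.2, 37.6, 53.8 and 37.0 CPM in KO against 55.0 to 68.0 CPM in WT, and after IL-4 at 31.9 to 34.8 CPM against 49.2 to 58.2 CPM. The value of 53.8 CPM rests on 9 counts in shallow library 7. Counts cover the whole gene (chromosome X, 101640011 to 101684351). The deleted part is not given in the sources used here, so these values do not measure it alone. The interaction terms of Ogt were not called (-0.14 ± 0.092 for LPS, adjusted p = 0.34, and -0.22 ± 0.080 for IL-4, 0.187).

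Mgea5, which encodes the enzyme that removes O-GlcNAc (OGA), was also lower in KO, by -0.47 ± 0.055 in M0 (adjusted p = 1.08e-06), -0.35 ± 0.069 in LPS (0.00037) and -0.47 ± 0.055 in IL-4 (6.42e-07) on the log2 scale. Of the 14 genes of O-GlcNAc cycling and the hexosamine pathway, 3 were higher and 3 lower in KO M0 (camera adjusted p = 0.484, median positive and test downward), 2 higher and 3 lower in LPS (0.198), and 5 higher and 3 lower in IL-4 (0.583). Gnpda1, a glucosamine-6-phosphate deaminase, was higher in M0 (0.32 ± 0.079, adjusted p = 0.00483) and in IL-4 (0.44 ± 0.079, 0.000123). Gfpt1, the enzyme at the entry of the hexosamine pathway, was higher in LPS (0.45 ± 0.098, 0.00102) and in IL-4 (0.37 ± 0.078, 0.000622). Rps6kb1, which encodes S6 kinase 1, was not called in any state with all libraries (0.17, 0.083 and 0.14, adjusted p = 0.119, 0.569 and 0.146). Without KO numbers 5 and 6 it was called higher in M0 (0.24, 0.016).

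**Figure D2:**
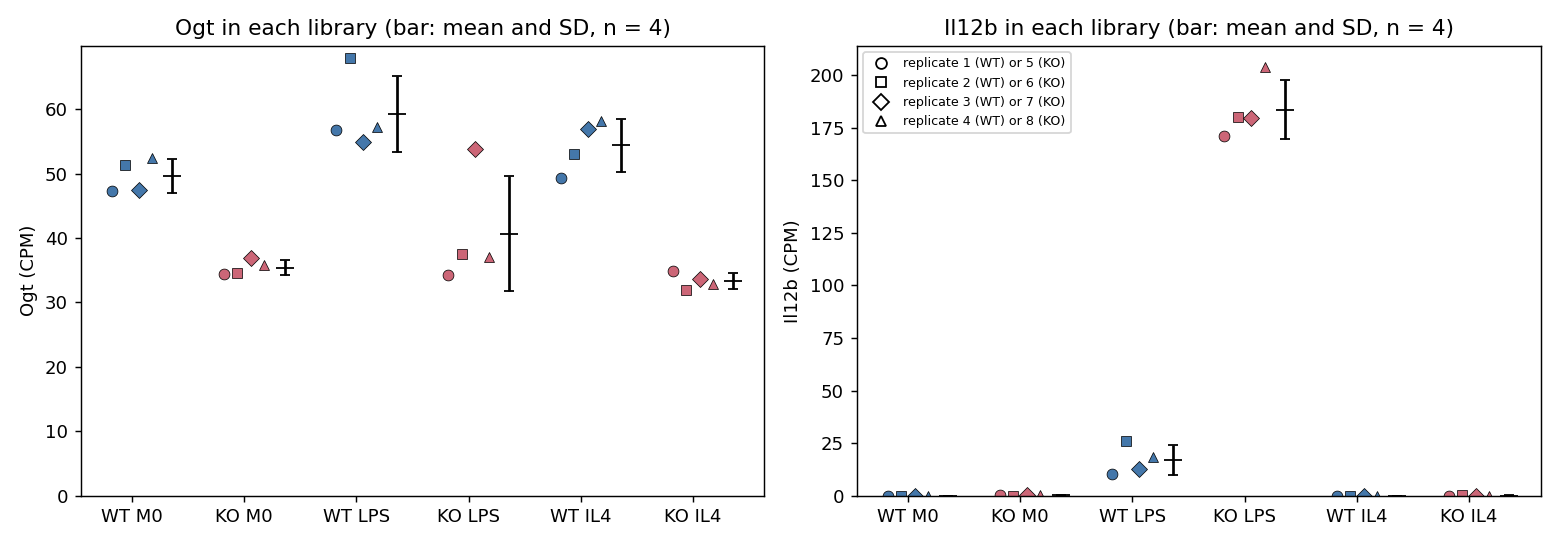
Ogt and Il12b in CPM per library for the 6 groups, with bars at the mean ± SD (n = 4). Ogt lies at 31.9 to 53.8 CPM in KO and 47.3 to 68.0 CPM in WT libraries, and after LPS Il12b lies at 171 to 204 CPM in KO and 10.3 to 26.2 CPM in WT.

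In unstimulated cells, camera with a preset correlation called NF-kB feedback, mitosis and osteoclast lists lower and amino acid response and stromal lists higher in KO than in WT. No list passed with an estimated correlation, where 6 lists had an unadjusted p under 0.05. Of 14693 genes, 1738 were higher and 1541 lower in KO, 261 and 67 of them at least 2-fold. For 3985 genes (27.1%, where chance gives 2.86% for independent libraries) the 4 KO values lay beyond all 4 WT values, among them 2840 of the 3279 called genes. Among genes with at least 5 CPM and no overlap between genotypes, Mmp9, which encodes a matrix gelatinase, fell most, from 34.0 ± 8.47 to 4.65 ± 0.992 CPM (log2 fold change -2.86 ± 0.16, adjusted p = 2.74e-12). Ccr1, a chemokine receptor, fell from 68.4 ± 3.74 to 26.2 ± 1.19 CPM (-1.38 ± 0.065, 1.08e-13). Gpr84, a receptor for medium-chain fatty acids, fell (-1.83 ± 0.17), as did Acp5, the tartrate-resistant acid phosphatase of osteoclasts (-1.58 ± 0.20). The other named genes that fell were Ptgs1, which encodes COX-1 (-1.47 ± 0.11), Bank1 (-1.42 ± 0.26), the integrin gene Itgal (-1.34 ± 0.21) and the inhibitory lectin Siglece (-1.26 ± 0.18). Their adjusted p were at most 0.000344. Lrrc14b rose from 0.813 ± 0.200 to 6.46 ± 0.358 CPM (2.99 ± 0.23, 8.4e-10) and Pcp4l1 from 8.02 ± 1.48 to 37.8 ± 4.46 CPM (2.23 ± 0.17, 9.98e-10). Fndc1 (2.33 ± 0.23), Ibsp, a bone sialoprotein (2.23 ± 0.22), and the collagen gene Col8a2 (2.16 ± 0.26) also rose, with adjusted p of at most 1.85e-06. Igfbp3 (3.52 ± 0.63), the Notch target Heyl (3.02 ± 0.70) and the imprinted gene Mest (2.85 ± 0.47) rose with a wide spread. Igfbp3 stood at 1.01, 1.73, 16.1 and 12.8 CPM in KO libraries 5 to 8. With number pairs summed, the calls of Igfbp3, Heyl, Mest and Bank1 ended (adjusted p = 0.0627, 0.183, 0.0598 and 0.104). In that setting 285 genes were higher and 272 lower. The higher count was 1145 without WT M0 replicate 3 and 1113 without KO M0 replicate 7. DESeq2 called 767 higher and 671 lower.

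NF-kB feedback genes, which NF-kB itself induces, were lower in KO M0. Of 25 genes 13 fell, also when adjusted over the list alone, and the other 12 did not pass (camera adjusted p = 5.13e-11, adjusted p = 0.179 with an estimated correlation). They include Nfkbia, the gene of the inhibitor IkB-alpha (-0.62 ± 0.077), the adhesion gene Icam1 (-0.55 ± 0.071) and the subunit genes Relb (-0.57 ± 0.080) and Nfkb2 (-0.37 ± 0.064). Of 25 proinflammatory cytokine and chemokine genes, 7 were lower and 3 higher (9 and 4 adjusted over the list alone, camera adjusted p = 0.00798, adjusted p = 0.392 with an estimated correlation). Lowest in adjusted p were the neutrophil attractant Cxcl2 (-1.25 ± 0.17), the monocyte attractants Ccl7 (-1.07 ± 0.15) and Ccl2 (-0.70 ± 0.11) and Tnf (-0.47 ± 0.12). Of 28 M1 markers, 9 were lower and 2 higher (9 and 4 over the list alone, camera 7.52e-05, 0.309 with an estimated correlation). Among them were Cd38 (-0.57 ± 0.082), Clec4e (-1.04 ± 0.19), Gch1 (-0.39 ± 0.077) and, upward, the pentraxin Ptx3 (0.57 ± 0.11). Of 44 interferon-stimulated genes 13 were lower and 1 higher (15 and 1 over the list alone, camera 1.86e-05, 0.563 with an estimated correlation). Bst2 (-0.42 ± 0.080), Irf1 (-0.46 ± 0.089), Ifih1 (-0.45 ± 0.11) and Trim30a (-0.50 ± 0.12) came first. Without WT M0 replicate 1, 5 interferon-stimulated genes were lower. Of the 44, 21 differed by label number within KO and 3 within WT.

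The amino acid response to ATF4 was higher in KO M0, where 17 of 30 genes rose and 1 fell (20 and 1 adjusted over the list alone, camera adjusted p = 5.13e-11, adjusted p = 0.179 with an estimated correlation). Its first members were Trib3 (0.75 ± 0.084), the leucine transporter gene Slc7a5 (0.68 ± 0.078), Vldlr (0.62 ± 0.074) and Chac1 (0.78 ± 0.10), with adjusted p between 5.1e-07 and 4.74e-06. Of 38 mitosis and DNA replication genes 26 were lower (32 over the list alone, camera 5.25e-07, 0.179 with an estimated correlation). Nusap1 (-0.41 ± 0.076), Aurkb (-0.47 ± 0.093), E2f1 (-0.39 ± 0.081) and Ube2c (-0.39 ± 0.083) led these. NRF2 targets fell (8 of 22, 9 over the list alone, camera 2.12e-06, 0.293), led by the glutathione reductase gene Gsr (-0.34 ± 0.065). Camera also called ER chaperones lower (4 lower and 1 higher of 20, 5 and 1 over the list alone, 6.32e-05, 0.234), and likewise cholesterol biosynthesis (4 lower of 24, 0.00137, 0.403) and ribosomal proteins, where 31 of 34 genes did not pass (3 lower, 2 over the list alone, 2.82e-05, 0.523). Of the 24 cholesterol genes, 20 differed by label number within KO and 0 within WT. LXR targets rose (5 higher and 1 lower of 19, 0.0305, 0.523), led by the phospholipid transfer protein gene Pltp (1.20 ± 0.080, adjusted p = 1.24e-10) and the sterol exporter gene Abcg1 (0.90 ± 0.066). Lysosome genes rose as well (7 and 3 of 30, 10 and 5 over the list alone, 0.00258, 0.563), led by Gusb (0.66 ± 0.064), as did ribosome biogenesis (8 of 23, 0.000725, 0.309), led by Gnl3 (0.39 ± 0.063). IL-4 markers (2 higher and 6 lower of 32, 0.694), heat shock proteins (2 higher of 15, 0.631) and glycolysis (3 and 2 of 22, 0.619) were not called. Neither were oxidative phosphorylation (4 and 4 of 30, 0.553), insulin and mTOR signalling (2 and 1 of 27, 0.687) or p53 targets (2 and 2 of 19, 0.564).

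Macrophage identity genes were lower in KO M0 (7 lower and 1 higher of 23, camera adjusted p = 4.1e-06, adjusted p = 0.37 with an estimated correlation). Lyz2, the macrophage lysozyme, fell from 9307 ± 592 to 5086 ± 399 CPM (-0.87 ± 0.072, adjusted p = 4.28e-09), Lyz1 by -0.84 ± 0.10, the fractalkine receptor gene Cx3cr1 by -1.18 ± 0.16 and Itgam by -0.59 ± 0.099. Lyz1 and Lyz2 are close copies, so reads may be shared between them. Osteoclast markers were lower (4 of 8, camera 0.000334, 0.179 with an estimated correlation, fry adjusted p = 0.0121). Mmp9, Acp5, Ocstamp (-2.41 ± 0.33) and Dcstamp (-1.68 ± 0.43) were called. Stromal markers were higher (7 of 10, 8 higher and 1 lower over the list alone, camera 2.89e-09, 0.123 with an estimated correlation, fry 0.0121). The collagen genes Col1a1 (0.66 ± 0.10), Col1a2 (0.58 ± 0.098) and Col3a1 (0.51 ± 0.11) and Lum (2.25 ± 0.35) came first. Lum was low, at 0.918 CPM in KO and 0.195 CPM in WT. Endothelial markers were higher (5 of 8, 6 over the list alone, 0.002, 0.386), led by Egfl7 (2.01 ± 0.22, adjusted p = 3.34e-07). Of these 8 genes, 7 differed by label number within KO and 0 within WT, and Cdh5 stood at 3.46, 4.99, 22.3 and 21.9 CPM in KO libraries 5 to 8, against 3.73 to 4.76 CPM in WT. Fry called 2 lists in M0.

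After LPS, KO macrophages held more Il12b and Nos2 mRNA than WT and less Mmp9 and Cx3cr1 mRNA. Camera with a preset correlation called interferon-stimulated, cytokine, glycolysis and amino acid response lists higher and the mitosis list lower. With an estimated correlation no list passed or had an unadjusted p under 0.05. Of 14693 genes, 2384 were higher and 2150 lower in KO, 405 and 135 of them at least 2-fold. The 4 values of each genotype did not overlap for 1891 genes (12.9%, chance 2.86%), among them 1490 of the 4534 called. In the 3 shallow libraries 0 counts allow up to 15.5 to 17.9 CPM, so this count is uncertain for genes under that level, such as Gbp11 and Ly6i. Il12b, the p40 subunit of IL-12 and IL-23, stood at 184 ± 14.0 CPM in KO and 16.95 ± 7.04 CPM in WT (3.56 ± 0.24, adjusted p = 5.2e-11). Its single values were 171, 180, 179 and 204 CPM in KO against 10.3, 26.2, 12.8 and 18.6 CPM in WT. Nos2, the inducible nitric oxide synthase, stood at 428 ± 154 against 93.1 ± 13.9 CPM (2.20 ± 0.23, 9.75e-08). Its values in KO libraries 5 to 8 were 555, 556, 245 and 354 CPM. Clic5 (3.02 ± 0.24), the macrophage-secreted Cd5l (2.67 ± 0.14) and the mitochondrial acetyl-CoA synthetase gene Acss1 (2.27 ± 0.16) also rose. So did the iron exporter gene Slc40a1 (2.15 ± 0.28), the heat shock gene Hspa1a (2.095 ± 0.19) and the guanylate-binding Gbp11 (2.09 ± 0.39), with adjusted p of at most 0.00027. Hspa1a has a near-identical copy, Hspa1b, and Gbp11 has close paralogs, so reads may be shared within each family.

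Among genes with at least 5 CPM and no overlap between genotypes, Mmp9 again fell most in LPS, from 155 ± 38.8 to 24.3 ± 4.47 CPM (-2.76 ± 0.18, adjusted p = 3.44e-11). Cx3cr1 fell from 125 ± 50.5 to 29.2 ± 11.3 CPM (-2.04 ± 0.20, 3.97e-08) and Siglece from 257 ± 31.4 to 77.8 ± 16.9 CPM (-1.56 ± 0.18, 6.28e-07). The amplifying receptor gene Trem1 (-1.55 ± 0.31), the inflammasome gene Nlrp1a (-1.504 ± 0.35), Ly6i (-1.49 ± 0.35), Btbd11 (-1.48 ± 0.19) and the scavenger receptor gene Marco (-1.42 ± 0.37) also fell, with adjusted p of at most 0.00485. Marco stood at 122, 124, 281 and 285 CPM in KO libraries 5 to 8 and 438 to 588 CPM in WT. Its call ended without KO numbers 5 and 6 (-0.74, adjusted p = 0.167). With number pairs summed, the calls of Marco (0.114) and Nlrp1a (0.0549) ended, and 1142 genes were higher and 946 lower. The lower count was 1278 without WT LPS replicate 3, 1275 without WT LPS replicate 4 and 1046 in DESeq2.

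Of 44 interferon-stimulated genes, 21 were higher in KO LPS (22 adjusted over the list alone, camera adjusted p = 0.000821, adjusted p = 0.696 with an estimated correlation). They were led by the immunity GTPase gene Irgm1 (0.74 ± 0.093), Isg20 (0.55 ± 0.086), the transcription factor gene Irf1 (0.57 ± 0.11) and Gbp3 (0.69 ± 0.13). Of 25 cytokine genes 10 were higher (11 over the list alone, camera 0.021, 0.696), such as the chemokine gene Ccl3 (0.74 ± 0.084), the IL-12 family member Il27 (1.35 ± 0.18) and endothelin Edn1 (1.34 ± 0.20). Of 28 M1 markers 8 were higher and 5 lower (camera 0.772), with Ptx3 (1.39 ± 0.14), the costimulatory receptor gene Cd40 (1.07 ± 0.11) and Procr (1.35 ± 0.16) beside Nos2. NF-kB feedback genes rose in 12 of 25 (14 over the list alone) without a list call (camera 0.0528, fry 0.0612). Those that rose include Nfkbib (0.72 ± 0.097), the phosphatase gene Dusp1 (0.67 ± 0.12), Il10 (1.49 ± 0.29) and Tnip1 (0.36 ± 0.073). IL-4 markers rose in 10 of 32 (camera 0.0704, fry 0.0358), led by the chemokine gene Ccl22 (2.02 ± 0.23) and the mannose receptor gene Mrc1 (0.88 ± 0.16). Without the 3 shallow libraries, 14 interferon-stimulated genes were higher.

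Amino acid response genes were higher in KO LPS in 20 of 30 cases (21 adjusted over the list alone, camera adjusted p = 0.000213, adjusted p = 0.696 with an estimated correlation), led by Vldlr (1.17 ± 0.097) and the stress factor gene Ddit3 (0.84 ± 0.086). Glycolysis and hypoxia genes rose (12 higher and 1 lower of 22, 12 and 2 over the list alone, camera 0.014, 0.696). The oxidase gene Ero1l (0.74 ± 0.071), the HIF hydroxylase gene Egln3 (1.23 ± 0.13), adrenomedullin Adm (0.94 ± 0.11) and the phosphofructokinase gene Pfkp (0.74 ± 0.085) came first. Lysosome genes rose (17 and 1 of 30, 18 and 2 over the list alone, 0.000821, 0.696), led by Gpnmb (0.64 ± 0.080) and the acid lipase gene Lipa (0.87 ± 0.11), while the sialidase gene Neu1 fell (-0.69 ± 0.088). Stromal markers rose (6 of 10, 0.013, 0.696), led by Col1a2 (0.56 ± 0.10) and Cxcl12 (0.96 ± 0.18). Mitosis genes fell (20 lower and 2 higher of 38, 22 and 3 over the list alone, 0.000821, 0.696), led by Cdc20 (-0.65 ± 0.089), E2f1 (-0.73 ± 0.10) and Plk1 (-0.75 ± 0.11). ER chaperones fell too (6 of 20, 5 over the list alone, 0.00149, 0.696), led by Hyou1 (-0.43 ± 0.055). Camera called 8 lists and fry 11. Lists not called by camera were p53 targets (7 higher and 1 lower of 19, 9 and 1 over the list alone, 0.102), with Plk2 (1.21 ± 0.12) and the death receptor gene Fas (1.03 ± 0.11) higher, and NRF2 targets (10 of 22, 11 over the list alone, 0.209), with Srxn1 (0.74 ± 0.067) higher. Heat shock proteins (5 and 3 of 15, 0.198), insulin and mTOR signalling (7 and 4 of 27, 0.296) and macrophage identity (6 and 8 of 23, 0.05, median upward and test downward) were not called either. The same holds for oxidative phosphorylation (3 and 6 of 30, 0.16), cholesterol biosynthesis (5 lower of 24, 3 over the list alone, 0.0751) and LXR targets (5 and 3 of 19, 0.96, median downward and test upward). It also holds for ribosome biogenesis (2 and 6 of 23, 0.0966), ribosomal proteins (2 and 5 of 34, 0.161), endothelial markers (3 higher of 8, 0.0722) and osteoclast markers (3 lower of 8, 0.198). Lyz2 fell from 8314 ± 252 to 3700 ± 193 CPM (-1.17 ± 0.074, 3.44e-11).

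After IL-4, the mitosis list was lower and the stromal list higher in KO than in WT, both also with an estimated correlation. Ribosomal protein, oxidative phosphorylation and IL-4 marker lists (lower) and LXR target and lysosome lists (higher) were called by camera with a preset correlation and did not pass with an estimated one. Of 14693 genes, 2632 were higher and 2675 lower in KO, 332 and 70 of them at least 2-fold. The genotypes did not overlap for 5451 genes (37.1%, chance 2.86%), among them 4525 of the 5307 called. By the same rule on CPM and overlap, Pcp4l1 rose most, from 1.37 ± 0.216 to 9.80 ± 3.25 CPM (2.84 ± 0.20, adjusted p = 2.11e-10). Cd5l rose from 17.7 ± 2.37 to 69.9 ± 5.78 CPM (1.98 ± 0.10, 7.53e-13), and the fatty acid-binding protein gene Fabp3 from 4.92 ± 0.152 to 18.5 ± 0.808 CPM (1.91 ± 0.082, 2.62e-14). Pianp (1.98 ± 0.14), the arginine deiminase genes Padi4 (1.98 ± 0.21) and Padi2 (1.78 ± 0.15), the cell cycle inhibitor gene Cdkn1c (1.84 ± 0.27) and Mamdc2 (1.84 ± 0.21) also rose. Their adjusted p were at most 1.14e-05. Mmp9 fell from 15.9 ± 1.48 to 3.87 ± 0.699 CPM (-2.04 ± 0.16, 2.04e-09), and the eosinophil attractant Ccl24 from 114 ± 16.1 to 47.8 ± 20.6 CPM (-1.26 ± 0.20, 4.01e-05). H2-Ke6 (-1.17 ± 0.10), complement C3 (-1.14 ± 0.21), Itgal (-1.10 ± 0.21), Id1 (-1.10 ± 0.25), the cholesterol hydroxylase gene Ch25h (-1.08 ± 0.12) and the kinase gene Fgr (-1.08 ± 0.15) also fell. Their adjusted p were at most 0.0013. With number pairs summed, the call of Id1 ended (0.086) and 934 genes were higher and 896 lower. DESeq2 called 1482 higher and 1309 lower.

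Mitosis and DNA replication genes fell in 37 of 38 cases in KO IL-4, also when adjusted over the list alone (camera adjusted p = 1.22e-14, adjusted p = 0.0346 with an estimated correlation). They were led by the replication helicase genes Mcm4 (-0.66 ± 0.065), Mcm7 (-0.61 ± 0.074) and Mcm5 (-0.72 ± 0.087) and by cyclin E1, Ccne1 (-0.71 ± 0.073). Stromal markers rose in 9 of 10 cases (camera 1.63e-10, 0.037 with an estimated correlation), led by Col3a1 (0.81 ± 0.11) and Col1a2 (0.67 ± 0.098). With an estimated correlation only these 2 passed. Within KO, 5 of the 10 stromal and 14 of the 38 mitosis genes differed by label number (0 and 3 within WT), against 2271 of all 14693 genes. Ribosomal proteins fell in 27 of 34 cases (29 over the list alone, 4.6e-24, 0.119), led by Rpl13 (-0.48 ± 0.065) and Rps4x (-0.46 ± 0.072). Oxidative phosphorylation and TCA genes fell in 16 of 30 (17 over the list alone, 1.05e-07, 0.172), led by Ndufv1 (-0.56 ± 0.056), Fh1 (-0.47 ± 0.048) and the citrate synthase gene Cs (-0.43 ± 0.059). Ribosome biogenesis fell in 11 of 23 (0.000235, 0.255), led by Dkc1 (-0.49 ± 0.074). IL-4 markers fell in 16 of 32 and rose in 2 (18 and 2 over the list alone, 0.00198, 0.609), led by Ch25h, Ptgs1 (-0.93 ± 0.10), Socs2 (-0.58 ± 0.078) and the transglutaminase gene Tgm2 (-0.64 ± 0.096).

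ER chaperones (7 lower and 1 higher of 20, 8 and 1 adjusted over the list alone, camera adjusted p = 0.000232, adjusted p = 0.255 with an estimated correlation), NRF2 targets (10 and 1 of 22, 11 and 1 over the list alone, 0.000851, 0.609) and NF-kB feedback genes (6 and 1 of 25, 0.00617, 0.726) were lower in KO IL-4. Hyou1 (-0.31 ± 0.046), Gpx4 (-0.43 ± 0.085) and Icam1 (-0.46 ± 0.072) came first in each. LXR targets were higher (9 and 1 of 19, 9 and 2 over the list alone, 0.000182, 0.255), led by Pltp (1.65 ± 0.082, adjusted p = 4.37e-13) and the desaturase gene Fads2 (0.69 ± 0.098). Lysosome genes were higher as well (12 and 2 of 30, 13 and 2 over the list alone, 0.000232, 0.609). Interferon-stimulated genes rose in 8 of 44 (1 over the list alone, 0.104), with Isg20 (0.63 ± 0.086) first. Amino acid response genes rose in 10 with 1 lower of 30 (11 and 1 over the list alone, 0.0784), with Vldlr (0.91 ± 0.076) first. Neither list was called. Cytokines (4 higher and 6 lower of 25, 0.333), M1 markers (3 and 3 of 28, 0.317), heat shock proteins (1 and 6 of 15, 0.114) and glycolysis (6 and 5 of 22, 0.518) were not called. Nor were insulin and mTOR signalling (6 and 2 of 27, 0.349), p53 targets (4 and 1 of 19, 0.208), macrophage identity (4 and 4 of 23, 0.966), cholesterol biosynthesis (3 lower of 24, 0.0603), endothelial (4 higher of 8, 0.0606) or osteoclast markers (1 and 2 of 8, 0.349). Fry called 5 lists. Lyz2 fell from 3231 ± 258 to 2353 ± 168 CPM (-0.46 ± 0.072, 2.86e-05).

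**Figure D3:**
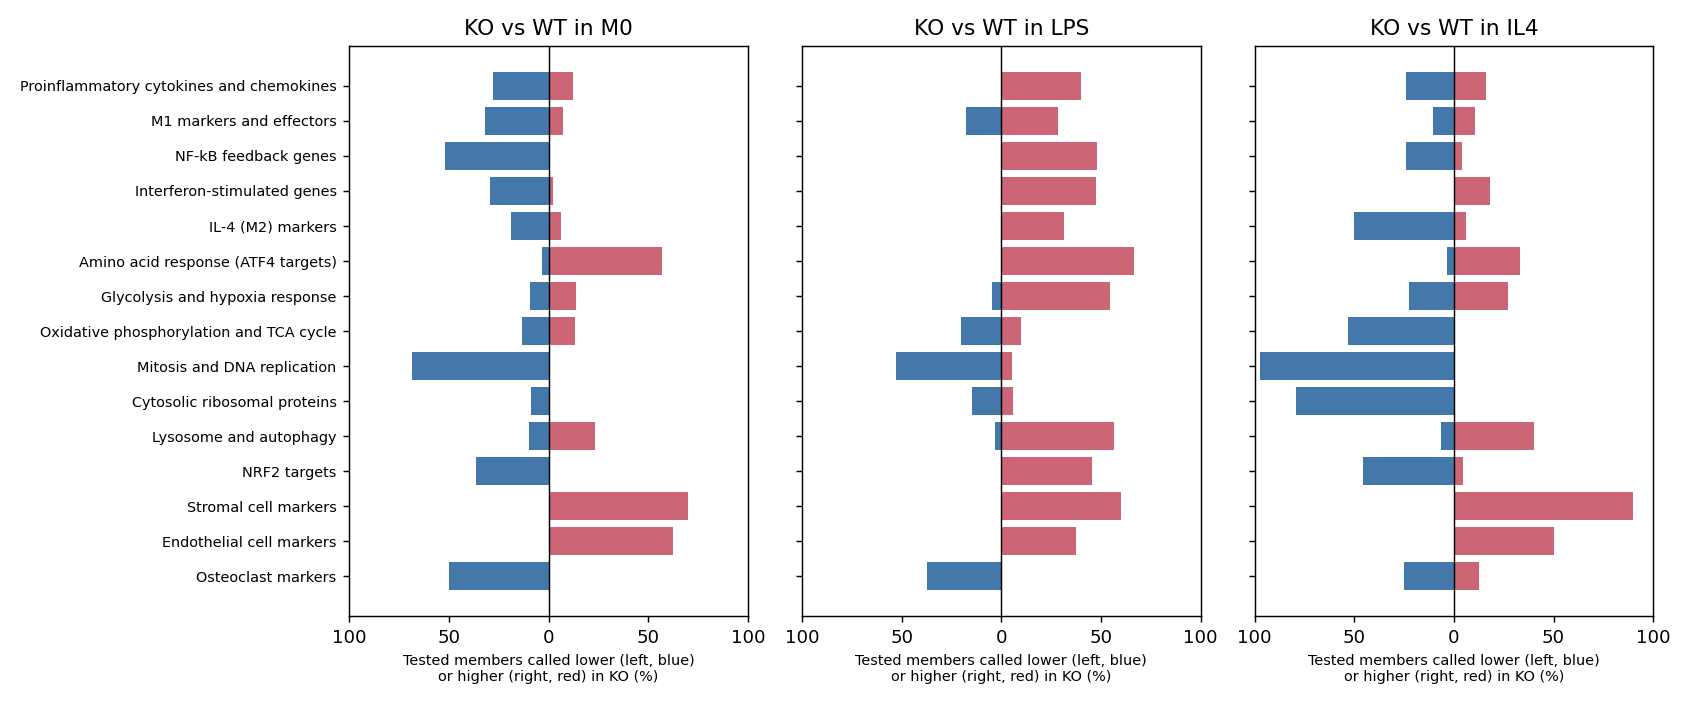
Percent of the tested genes of 15 lists called lower (left, blue) and higher (right, red) in KO than in WT, for M0, LPS and IL-4. NF-kB feedback genes go lower in M0 (13 of 25) and higher in LPS (12 of 25), and mitosis genes are lower in all 3 states (26, 20 and 37 of 38).

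In all 3 states 596 genes were higher in KO (51 if calls were independent) and 629 lower (41). Label numbers recur across states in a single fit, so independence is no null. Mmp9 was lower and Pltp higher in every state. Between M0 and LPS, 39 genes called higher in M0 were called lower in LPS. Another 85 called lower in M0 were called higher in LPS, Icam1 and Irf1 among these.

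LPS raised cytokine, M1, NF-kB feedback and interferon-stimulated genes in both genotypes. In WT 4320 genes were higher and 4152 lower than in M0 (1501 and 1295 at least 2-fold). In KO 4591 were higher and 5294 lower (1814 and 1634). Ccl5 rose from 2.47 ± 3.07 to 2978 ± 446 CPM in WT (10.24 ± 0.74, adjusted p = 4.52e-12). The acute-phase gene Saa3 rose from 22.5 ± 31.3 to 24870 ± 2496 CPM, Ifi205 from 0.276 ± 0.0909 to 237 ± 112 CPM and Cxcl10 from 1.56 ± 1.29 to 1684 ± 205 CPM. Nos2 rose by 9.98 ± 0.35 in WT and 10.53 ± 0.30 in KO, Il1b by 9.10 ± 0.42 and 9.92 ± 0.45, Il6 by 6.24 ± 0.22 and 7.50 ± 0.23, and Tnf by 4.80 ± 0.13 and 5.43 ± 0.13. Il12b went from 0.0349 to 16.95 CPM in WT and from 0.176 to 184 CPM in KO. Cxcl11 went from 0.0208 to 60.8 CPM and from 0.0435 to 83.4 CPM. In KO, Cxcl9 rose by 10.57 ± 0.49, Cxcl10 by 10.44 ± 0.54, Saa3 by 10.55 ± 0.97 and the itaconate synthase gene Irg1 by 10.51 ± 0.69. Gstt4 went from 0.00505 to 15.2 CPM. Arg1 rose by 3.46 ± 0.23 and 3.11 ± 0.21 and Mrc1 fell (-4.36 ± 0.17 and -3.21 ± 0.14). Retnla (adjusted p = 0.753 and 0.708) and Chil3 (0.5 and 0.418) were not called. Without WT LPS replicate 3, Chil3 was called higher in WT (0.78, 0.029).

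The transporter gene Slco2b1 fell from 43.5 to 0.0575 CPM with LPS in WT and by -7.27 ± 0.25 in KO. The purinergic-type receptor gene Gpr34 fell by -6.85 ± 0.26 and -5.71 ± 0.19, Cd28 by -6.33 ± 0.19 and -5.68 ± 0.15, the lectin gene Clec10a by -5.46 ± 0.40 and -4.51 ± 0.29 and Slc46a3 by -4.76 ± 0.18 and -4.22 ± 0.14. Asb10 went from 5.16 to 0.0303 CPM in WT, and Reps2 fell by -4.39 ± 0.11 in KO. All 44 interferon-stimulated genes and all 25 NF-kB feedback genes rose in both genotypes. So did 23 of 25 cytokine genes in WT and 25 in KO, and 27 of 28 M1 markers in WT and 28 in KO. Isg20, Herc6, Gbp3 and Mx2 led the interferon-stimulated genes, and Traf1 (6.43 ± 0.14 in WT, 7.73 ± 0.14 in KO) the NF-kB feedback genes. These 4 lists and glycolysis (20 higher and 1 lower of 22 in WT, 22 higher in KO) passed with an estimated correlation in both genotypes. Their adjusted p lay between 0.00166 and 0.0237 in WT and between 0.000963 and 0.0113 in KO. Mitosis genes fell in 35 of 38 cases in WT (camera adjusted p = 1.98e-08, adjusted p = 0.052 with an estimated correlation) and in 35 with 2 higher in KO (4.24e-09, 0.0448), led by Ccna2 and Kif11 in WT. Camera also called ER chaperones (16 higher and 1 lower of 20 in WT, 1.14e-07, 15 and 1 in KO, 4.46e-06) and heat shock proteins (10 and 2 of 15, 0.00254, 10 and 3, 0.00217). It called NRF2 targets (14 and 4 of 22, 0.00018, 16 and 3, 1.38e-06) and, downward, cholesterol biosynthesis (17 lower of 24, 0.0441, 18 lower and 1 higher in KO, 0.0377). None of these 4 lists passed with an estimated correlation.

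IL-4 raised its marker genes together with ribosome biogenesis, oxidative phosphorylation and ER chaperone genes in both genotypes. In WT 4535 genes were higher and 4301 lower than in M0 (623 and 980 at least 2-fold). In KO 3825 were higher and 3709 lower (540 and 749). DESeq2 called 2949 higher in WT and 2145 higher in KO, and with number pairs summed 2139 were lower in KO. Retnla rose from 2.14 ± 2.41 to 4129 ± 273 CPM in WT (10.92 ± 0.91, adjusted p = 1.38e-10) and from 1.41 ± 1.5 to 2950 ± 1342 CPM in KO (11.02 ± 0.92, 2.25e-10). Arg1 rose by 9.30 ± 0.27 in WT and 8.90 ± 0.27 in KO, Chil3 by 8.79 ± 0.25 and 8.69 ± 0.25, and Mrc1 by 1.27 ± 0.12 and 1.45 ± 0.12. Genes near the floor in M0 rose too. From under 0.05 CPM, the ribonuclease gene Rnase2a rose to 124 CPM in WT and 110 CPM in KO, the homeobox gene Msx3 to 31.9 and 21.7 CPM and the sodium channel gene Scn3a to 30 and 25.4 CPM. Pdcd1lg2, which encodes PD-L2, rose from 0.0453 to 32.6 CPM in WT. Chil4 reached 5.45 ± 1.68 CPM in WT from 0 counts in all 4 M0 libraries. It is a close copy of Chil3, so reads may be shared. Cx3cr1 fell from 236 ± 9.56 to 5.17 ± 1.26 CPM in WT (-5.52 ± 0.19) and from 104 ± 6.03 to 2.46 ± 0.151 CPM in KO (-5.41 ± 0.20). Fcrl1 (-4.24 ± 0.23 and -3.77 ± 0.23), the purinergic receptor gene P2ry13 (-3.88 ± 0.14 and -3.40 ± 0.14) and Gpr162 (-3.73 ± 0.17 and -3.65 ± 0.16) fell in both, as did the lectin gene Clec4n (-3.73 ± 0.088 and -3.73 ± 0.091) and Gpr34 (-3.45 ± 0.14 and -3.05 ± 0.13). Tnf fell (-1.10 ± 0.13 and -0.90 ± 0.13), Il1b fell in WT (-2.31 ± 0.56, 0.000999) and Nos2 was not called in WT (adjusted p = 0.951). In WT, Il6 rose (1.31 ± 0.25) and Cxcl10 fell (-1.64 ± 0.60, 0.0212). The call of Cxcl10 ended without WT M0 replicate 1 (-0.93, 0.19) and without WT IL4 replicate 1 (-1.31, 0.0625). It also ended with number pairs summed (0.108). In KO, Il6, Il12b, Il1b, Nos2 and Cxcl10 stood under 2 CPM in M0 and IL-4. There Il6 rose (0.77 ± 0.30, 0.0363) and Il12b (-1.85 ± 0.72, 0.0334) and Cxcl10 (-1.73 ± 0.56, 0.0119) fell, while Nos2 (-1.44 ± 0.61, 0.0501) and Il1b (-1.26 ± 0.69, 0.134) were not called. The KO call of Il6 ended without KO M0 replicate 5 (0.128), 6 (0.0931) or 8 (0.0524) and KO IL4 replicate 6 (0.0912) or 8 (0.137), in DESeq2 (0.0697), with RLE factors (0.0502), and without KO numbers 5 and 6 (0.261) or 7 and 8 (0.062). That of Il12b ended without KO M0 replicate 5 (0.0709) or 7 (0.138) and KO IL4 replicate 5 (0.0624), 7 (0.0933) or 8 (0.0636), without KO numbers 7 and 8 (-0.41, 0.734), with only the groups compared (0.146) and in DESeq2 (0.0859). That of Cxcl10 ended without KO numbers 7 and 8 (-0.71, 0.341), with only the groups compared (0.0556) and with number pairs summed (0.103). Nos2 was called without KO M0 replicate 6 (0.00689) and KO IL4 replicate 5 (0.0452) or 6 (0.023), without KO numbers 5 and 6 (-3.11, 0.000835), with RLE factors (0.0376), with no filter (0.0471) and with the number as a block (0.0287). Il1b was called without KO M0 replicate 6 (0.0495).

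Of 32 IL-4 markers, 31 rose with IL-4 in WT and 1 fell, and in KO 31 rose (camera adjusted p = 3.25e-26 and 1.92e-32, adjusted p = 0.00598 and 0.00188 with an estimated correlation). They were led by Pdcd1lg2, the receptor gene Clec7a (2.40 ± 0.058 and 2.33 ± 0.057), Cish (4.51 ± 0.11 and 4.11 ± 0.11) and Egr2 (3.17 ± 0.082 and 3.15 ± 0.082). Ribosome biogenesis rose in 23 of 23 in both genotypes (0.00663 and 0.0321 with an estimated correlation), led by Nolc1 (1.24 ± 0.058 and 0.79 ± 0.057) and Dkc1 (1.52 ± 0.076 and 0.88 ± 0.076). Oxidative phosphorylation and TCA genes rose in 30 of 30 in WT and 27 in KO (0.00952 and 0.0498), led by Idh3a (0.86 ± 0.059 and 0.60 ± 0.058). ER chaperones rose in 18 of 20 in both (0.00663 and 0.00278), led by Pdia4 (1.92 ± 0.050 and 1.96 ± 0.050). Some lists were called by camera and did not pass with an estimated correlation. Those that rose were ribosomal proteins (33 higher of 34 in WT, 3.94e-13, 19 in KO, 2.14e-05), mitosis genes (34 higher of 38, 7.91e-08, 30 in KO, 3.29e-05), led by Pcna (1.05 ± 0.072 and 0.94 ± 0.072), and MHC class II genes (7 higher and 1 lower of 10 in both, 0.0396 and 0.0244), led by H2-DMa. Those that fell were interferon-stimulated genes (30 lower of 44, 1.43e-12, 20 in KO, 1.27e-06), M1 markers (16 of 28, 0.00045, 13 in KO, 0.00169) and NF-kB feedback genes (14 of 25, 0.00042, 12 in KO, 0.00806). So did macrophage identity (13 of 23, 8.6e-08, 12 in KO, 2.14e-05) and stromal markers (8 of 10, 1.98e-05, 8 in KO, 2.14e-05).

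The response to LPS differed between genotypes for single genes, and camera with a preset correlation called cytokine, NF-kB feedback, interferon-stimulated and NRF2 lists higher in the KO response. No list of this interaction passed with an estimated correlation, where 3 had an unadjusted p under 0.05. For 972 genes the KO response was higher than the WT response and for 704 it was lower (160 and 72 at least 2-fold). The chemokine genes Ccl20 (3.80 ± 0.84, adjusted p = 0.0057) and Ccl22 (2.58 ± 0.58, 0.00441) and Slc40a1 (2.55 ± 0.34, 2.51e-05) responded more in KO. So did the nuclease gene Dnase1l3 (2.48 ± 0.41, 0.000254), Acss1 (2.30 ± 0.19, 1.96e-08), the serpin gene Serpina3g (2.19 ± 0.28, 1.83e-05) and Il27 (2.03 ± 0.35, 0.000338). Serpina3g has the close copy Serpina3f, so reads may be shared. Spaca6 (-1.38 ± 0.30, 0.00285) and the calcium-binding membrane protein gene Mctp1 (-1.35 ± 0.19, 3.74e-05) responded less in KO. Lrrc14b was also called (-2.02 ± 0.50, 0.00938), but not without WT LPS replicate 4 (-0.27, 0.901). Further calls that end without a single library are Ip6k3 (-1.83 ± 0.48, 0.0128, without WT LPS replicate 4 adjusted p = 0.0757), Tspan18 (-1.5 ± 0.36, 0.00679, without WT LPS replicate 3 adjusted p = 0.0554) and Padi2 (-1.33 ± 0.28, 0.00223, without WT LPS replicate 3 adjusted p = 0.137). The lower count was 225 without WT LPS replicate 3, 263 without WT LPS replicate 4 and 388 without KO LPS replicate 6. DESeq2 called 643 higher and 215 lower, and with number pairs summed 58 were higher and 7 lower. With the number as a block 1620 were higher and 1367 lower, and without KO numbers 7 and 8 1548 were higher. The calls of Ccl20 (adjusted p = 0.161), Slc40a1 (0.0705), Serpina3g (0.0504), Il27 (0.0553) and Spaca6 (0.0705) ended with number pairs summed, as did those of Ip6k3 (0.238), Tspan18 (0.26) and Padi2 (0.109).

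NF-kB feedback genes responded more to LPS in KO in 15 of 25 cases (17 adjusted over the list alone, camera adjusted p = 9.71e-09, adjusted p = 0.513 with an estimated correlation). They were led by Icam1 (0.89 ± 0.11), Traf1 (1.30 ± 0.19), Dusp1 (1.03 ± 0.16) and Tnip3 (1.99 ± 0.34). Interferon-stimulated genes did so in 14 of 44 (21 over the list alone, 2.4e-09, 0.747), led by Irf1 (1.03 ± 0.14) and Irgm1 (0.79 ± 0.12). Cytokines did so in 11 with 1 lower of 25 (15 and 1 over the list alone, 4.54e-05, 0.513), led by Ccl2 (1.06 ± 0.16), Ccl7 (1.29 ± 0.21) and Csf1 (0.78 ± 0.13). M1 markers (10 and 2 of 28, 11 and 2 over the list alone, 0.00396, 0.747) were led by Cd40 (1.15 ± 0.15) and the COX-2 gene Ptgs2 (1.97 ± 0.36). NRF2 targets (10 of 22, 12 over the list alone, 0.00015, 0.747) were led by the heme oxygenase gene Hmox1 (1.08 ± 0.13) and Srxn1 (0.68 ± 0.086). Glycolysis genes (8 of 22, 11 over the list alone, 0.000686, 0.747) were led by Adm (1.51 ± 0.13) and Egln3 (1.37 ± 0.17). Higher in response were also p53 targets (6 of 19, 7 over the list alone, 0.0376, 0.747), led by Mdm2 (0.68 ± 0.079), IL-4 markers (10 of 32, 0.0376, 0.79), led by Ptgs1 (1.18 ± 0.19), and lysosome genes (5 and 1 of 30, 0.0482, 0.79), led by the autophagy receptor gene Sqstm1 (0.63 ± 0.098). Ribosome biogenesis (7 lower of 23, 0.00015, 0.513), led by Srm (-0.63 ± 0.12), had a lower response by camera. Camera also called oxidative phosphorylation downward (0.0433, 0.79), but 27 of 30 genes did not pass, 2 were lower and Uqcrfs1 was higher (0.33 ± 0.096). Fry called 3 lists of this interaction.

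The response to IL-4 differed between genotypes for 167 genes, 69 higher and 98 lower in KO (7 and 7 at least 2-fold), and 2079 had an unadjusted p under 0.05. Ocstamp, an osteoclast fusion gene (2.79 ± 0.37, adjusted p = 0.000128), Serpinb8 (1.06 ± 0.13, 8.79e-05) and Ptafr (0.95 ± 0.13, 0.000128) responded more in KO. So did Entpd1 (0.84 ± 0.11, 8.79e-05), Itgam (0.83 ± 0.14, 0.00303) and Cd33 (0.82 ± 0.13, 0.00136). Ocstamp was lower in KO M0 (-2.41) and not called in IL-4 (0.38). The purinergic receptor gene P2ry1 (-1.17 ± 0.15, 8.79e-05), Cdca7 (-0.95 ± 0.12, 8.79e-05), the VEGF receptor gene Flt1 (-1.87 ± 0.36, 0.0081) and Shmt1 (-0.81 ± 0.16, 0.00964) responded less. Without KO numbers 7 and 8 the calls of Flt1 (0.0935) and Shmt1 (0.113) ended, and in DESeq2 that of Entpd1 (0.423). With number pairs summed no gene was called by edgeR (795 at an unadjusted p under 0.05). DESeq2 on all libraries called 35 higher and 47 lower. With the number as a block 497 were higher and 621 lower, and without KO numbers 5 and 6 381 were higher and 296 lower. From the compared groups alone 135 were higher and 165 lower. Higher and lower counts were 31 and 40 without WT M0 replicate 1, 148 and 212 without WT M0 replicate 2, 27 and 33 without WT M0 replicate 3 and 43 and 48 without WT M0 replicate 4. They were 33 and 41 without KO M0 replicate 7, 30 and 38 without KO M0 replicate 8. They were 31 and 40 without WT IL4 replicate 1, 27 and 34 without WT IL4 replicate 2, 35 and 44 without WT IL4 replicate 4 and 35 and 37 without KO IL4 replicate 7. The lower count was 48 without KO IL4 replicate 8.

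Ribosome biogenesis responded less to IL-4 in KO (7 of 23 lower, 17 adjusted over the list alone, camera adjusted p = 1.73e-20, adjusted p = 0.00371 with an estimated correlation). They were led by Dkc1 (-0.63 ± 0.11), Nolc1 (-0.45 ± 0.081) and Gnl3 (-0.49 ± 0.088). Oxidative phosphorylation and TCA genes did too (3 of 30, 15 over the list alone, 4.52e-18, 0.0144), led by Sdhb (-0.32 ± 0.079) and Sdhd (-0.32 ± 0.079). IL-4 markers (5 lower of 32, 7 lower and 1 higher over the list alone, 0.000106, 0.301), led by Myc (-0.65 ± 0.11) and Socs2 (-0.56 ± 0.11), were lower in response by camera. So were amino acid response genes (4 of 30, 8 lower and 1 higher over the list alone, 4.24e-07, 0.258), led by Shmt2 (-0.46 ± 0.083). Mitosis genes (3 of 38, 9 over the list alone, 2.59e-07, 0.11) were led by Cdt1 (-0.54 ± 0.12). Ribosomal proteins (9.13e-23, 7 over the list alone, 0.105) and heat shock proteins (0.00141, 1 over the list alone, 0.258) were called downward by camera without a called gene. Macrophage identity (3 higher of 23, 4 over the list alone, 1.1e-10, 0.196), led by Itgam and Mpeg1 (0.55 ± 0.12), and osteoclast markers (2 of 8, 5 over the list alone, 3.24e-05, 0.105) were higher by camera. Of 25 NF-kB feedback genes (upward, 2.35e-05, 0.333) only Tnfaip2 (0.42 ± 0.10) was called. Camera called LXR targets upward (2 higher and 1 lower of 19, 4 and 1 over the list alone, 0.004, 0.33), with Fads2 (0.55 ± 0.14, adjusted p = 0.0485) and Pltp (0.45 ± 0.11, 0.0495) higher and Abcg1 (-0.74 ± 0.092, 8.79e-05) lower. Camera also called interferon-stimulated genes (5.21e-16, 0.258), M1 markers (0.0011, 1 over the list alone, 0.333), p53 targets (0.00511, 3 over the list alone, 0.33) and stromal markers (0.0262, 0.444) upward, but no gene of these lists was called and none of the lists passed with an estimated correlation. Fry called none and gave 3 lists an unadjusted p under 0.05.

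Markers of further cell types gave no list call between KO and WT. Of 12 neutrophil genes, 3 were higher and 1 lower in M0 (camera adjusted p = 0.26), 3 lower in LPS (0.83), and 1 higher and 1 lower in IL-4 (0.78). Mmp8 was lower in each state (-0.76 ± 0.14, -0.86 ± 0.18 and -0.61 ± 0.14) and the granule gene Mpo was higher in M0 (2.11 ± 0.62) and IL-4 (1.73 ± 0.63). Of 4 T and NK cell genes 1 was higher in each state (0.33, 0.218 and 0.78). Of 5 B cell genes 2 were higher in each state, with 1 lower in M0 and IL-4 (0.484, 0.294 and 0.349). Of 5 dendritic cell genes 1 was higher in LPS (0.459), with no call in M0 (0.936) or IL-4 (0.312). Of 4 mast cell and basophil genes 1 was higher and 1 lower in M0 (0.693), 1 lower in LPS (0.713) and 1 higher in IL-4 (0.953). Of 2 erythroid genes 1 was lower in LPS (0.58, with 0.718 in M0 and 0.571 in IL-4). Of 4 megakaryocyte genes 2 were lower in M0 (0.244, with 0.713 in LPS and 0.349 in IL-4). Of 10 MHC class II genes, H2-DMb2 was lower in M0 (-0.58 ± 0.21, list 0.718) and H2-Ab1 higher in IL-4 (0.23 ± 0.082, list 0.908). The list was not called in LPS (0.713). Both small structural RNAs were lower in LPS (0.483) and 1 was higher in IL-4 (0.464), with no call in M0 (0.953). Rn45s stood at 6616 CPM in WT LPS replicate 3 against 966 to 2846 CPM in the other WT and 951 to 1328 CPM in the KO LPS libraries, and at 3730 CPM in KO IL4 replicate 5 against 671 to 1477 CPM in the other IL-4 libraries. Without KO numbers 5 and 6, 0 of 2 RNAs passed in IL-4 and 1 in LPS. Among sex-linked genes Xist was tested, with -0.027 in M0 (adjusted p = 0.884), -0.37 ± 0.13 in LPS (0.0255) and 0.020 in IL-4. The mitochondrially encoded transcripts had no tested gene.

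Libraries of the same genotype differed by their label number. An F test on the number, adjusted for state, called 2271 genes within KO and 207 within WT. On chromosome 1 from 170 to 180 Mb, 42 of 90 tested genes were called within KO (14 by the genome-wide share, adjusted p = 8.24e-10) and 13 within WT (9.31e-08). Within WT a second window passed, on chromosome 9 from 60 to 70 Mb (7 of 68 genes, 0.956 by the genome-wide share, adjusted p = 0.00594), which did not pass within KO (20 of 68, 0.147). Between deep libraries of a group, the chi-square per degree of freedom was 7.65 to 28 within KO number pairs (5 with 6, 7 with 8) and 47 to 80.8 across them, against 11.2 to 32.2 and 12.1 to 32.9 in WT. The labels do not say whether the libraries of a pair share an animal or culture, and if they do, the p-values for KO over 4 libraries are too small. In the chromosome 1 window lies the interferon-inducible gene Ifi202b (173962569 to 173982844), chosen after its values were seen. Ifi202b stood at 0.0303, 0, 11.3 and 11.4 CPM in KO M0 libraries 5 to 8, at 0.314, 0.587, 257 and 240 CPM in KO LPS and at 0, 0.111, 12.7 and 13.3 CPM in KO IL-4. In WT libraries 1 to 4 Ifi202b stood at 14.7, 15.5, 4.95 and 6.12 CPM in M0, 237, 209, 76.5 and 78.4 CPM in LPS and 14.2, 15.2, 5.52 and 5.88 CPM in IL-4. Pcp4l1 also lies in the window (171173264 to 171196268). There 10 of the 90 genes were called higher and 6 lower in KO than in WT in M0, 13 and 10 in LPS and 17 and 9 in IL-4.

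**Figure D4:**
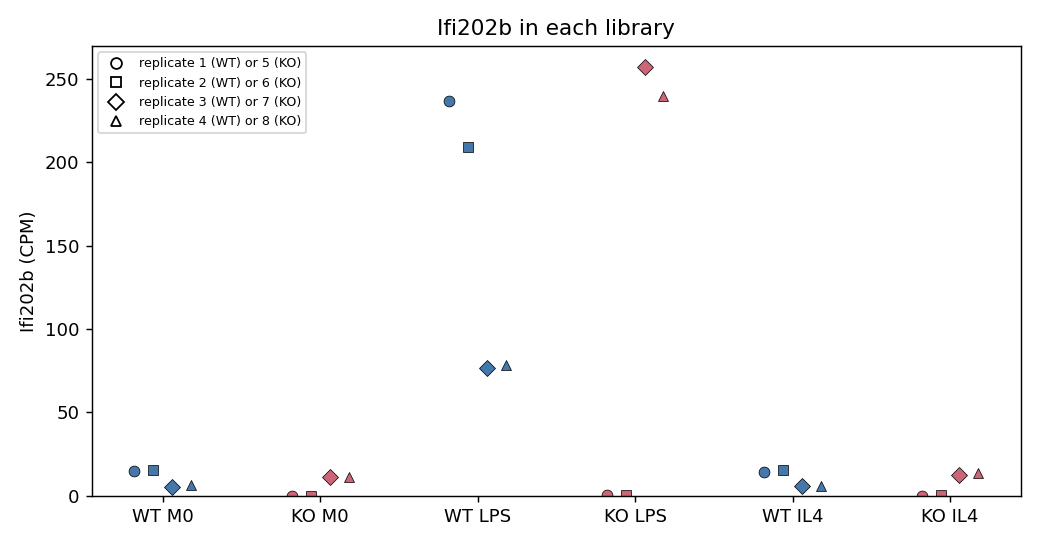
Ifi202b in CPM per library, by group, with 1 marker per label number. KO libraries 5 and 6 hold 0 to 0.587 CPM of Ifi202b and KO libraries 7 and 8 hold 11.3 to 257 CPM.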

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

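Counts over other splits of the libraries were chosen only after the results were seen for KO against WT in M0 and LPS and for the 4 stimulation contrasts, as were the tests with number pairs summed and without KO numbers 5 and 6 or 7 and 8. In 132 groups of 4 libraries, 8 held a library whose gap to the nearest other exceeded 0.829 of the range of the group. Chance gives this in about 1 in 20 groups, here 7. In 6 of the 8 the library was a shallow one, where a value rests on few counts. KO LPS replicate 7 held 0.173 M gene counts (M for 1e6), against 68.8 to 77.3 M in the others of its group. Rps6kb1 stood at 15.7 CPM in WT LPS replicate 2 (3 counts), against 29.7 to 31.1 CPM in the others, and at 65.8 CPM in KO LPS replicate 7 (11 counts), against 27.9 to 33.9 CPM. Slc40a1 had 0 counts in WT LPS replicate 1, which allows up to 15.5 CPM, against 9.93 to 11.3 CPM in the others. In WT LPS replicate 2, Trem1 stood at 10.5 CPM against 4.44 to 5.16 CPM and Btbd11 at 26.2 CPM against 4.05 to 5.16 CPM. The deep libraries were KO M0 replicate 5, with Ccr1 at 28.0 CPM against 25.5 to 25.8 CPM, and KO LPS replicate 8, with Cx3cr1 at 46.1 CPM against 22.3 to 24.4 CPM.

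The response to LPS differed between genotypes for 1676 genes by the interaction term, 972 higher and 704 lower in KO. Of 50 splits drawn within LPS and within M0, the real one included, 3 called as many genes, and the highest other split called 2692. That split exchanged the genotype of all 8 M0 libraries and kept it for 4 of 8 LPS libraries, and the next (2533) kept it for 2 of 8 LPS and 6 of 8 M0 libraries. Both carry genotype differences of M0, LPS or both into the interaction term, so these splits are no null for it and do not decide whether chance made the count. Among genes with at least 5 CPM, those with the largest higher responses in KO were Ccl20 (3.80), Ccl22 (2.58), Slc40a1 (2.55), Dnase1l3 (2.48), Acss1 (2.30), Serpina3g (2.19), Serpina3f (2.15) and Il27 (2.03) on the log2 scale. Those with the largest lower responses were Lrrc14b (-2.02), Ip6k3 (-1.83), Tspan18 (-1.5), Wisp1 (-1.39), Spaca6 (-1.38), Hey1 (-1.35), Mctp1 (-1.345) and Padi2 (-1.33). The call of Lrrc14b ended without WT LPS replicate 4 (adjusted p = 0.901), as did that of Ip6k3 (0.0757), and those of Tspan18 (0.0554) and Padi2 (0.137) ended without WT LPS replicate 3.

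Further calls of the LPS interaction rested on single libraries. Serpina3f (adjusted p = 0.034 with all libraries) ended without WT M0 replicate 4 (0.172), KO M0 replicate 7 (0.0619) or 8 (0.0615), WT LPS replicate 3 (0.0662) or 4 (0.0613), and KO LPS replicate 5 (0.0508) or 6 (0.0559). Wisp1 ended without WT M0 replicate 3 (0.0571), KO M0 replicate 7 (0.0714) or 8 (0.0641), WT LPS replicate 3 (0.161) or 4 (0.0621), and KO LPS replicate 5 (0.102) or 6 (0.0967). It also ended in DESeq2 (0.0648) and without the 3 shallow libraries (0.0617). Hey1 ended without WT LPS replicate 3 (0.1), KO LPS replicate 5 (0.0591) or 6 (0.0529), and Mctp1 ended in DESeq2 (0.0696).

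The response to IL-4 differed between genotypes for 167 genes by the interaction term, 69 higher and 98 lower in KO. Of 50 splits, the real one included, 2 called as many genes. The splits were drawn freely within each state, although deviations of KO M0 and IL-4 libraries of equal number correlated. With number pairs summed edgeR called 0 genes (795 at an unadjusted p under 0.05), where DESeq2 on all libraries called 35 and 47. The highest other split called 2705, many times the real count, and exchanged the genotype of all 8 M0 libraries while 6 of 8 IL-4 libraries kept it. It points to the genotype difference shared by both states, and every remaining split called at most 4. These splits are no null for the interaction either, so they do not decide whether chance made the count. Among genes with at least 5 CPM, higher responses in KO were largest for Ocstamp (2.785), Acp5 (1.08), Serpinb8 (1.06), Ptafr (0.95), BC021767 (0.92), Entpd1 (0.84), Itgam (0.83) and Cd33 (0.82). Lower responses were largest for Flt1 (-1.87), Lipn (-1.26), Cyp4f18 (-1.21), P2ry1 (-1.17), Socs1 (-1.155), Cdca7 (-0.95), Penk (-0.94) and Shmt1 (-0.81). Lyz2 was also called, with 0.41.

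Of these IL-4 calls, 7 ended without single libraries. Acp5 ended without WT M0 replicate 1, 3 or 4, KO M0 replicate 5, 6 or 8, any WT IL4 replicate, or KO IL4 replicate 7 or 8 (adjusted p from 0.0624 to 0.137). BC021767 ended without WT M0 replicate 3 (0.0547) and WT IL4 replicate 1 (0.0649) or 2 (0.0542). Lipn ended without WT M0 replicate 1 or 3, KO M0 replicate 5 or 7, WT IL4 replicate 1, 2 or 4, or KO IL4 replicate 7 (0.0503 to 0.111). Cyp4f18 ended without WT M0 replicate 1, 3 or 4, KO M0 replicate 7 or 8, any WT IL4 or any KO IL4 replicate (0.0616 to 0.136). Socs1 ended without WT M0 replicate 1, 3 or 4, KO M0 replicate 6, 7 or 8, WT IL4 replicate 1 or 2, or KO IL4 replicate 7 or 8 (0.0522 to 0.0932). Penk ended without WT M0 replicate 1, 3 or 4, KO M0 replicate 5, 6 or 8, any WT IL4 or any KO IL4 replicate (0.0503 to 0.103). Lyz2 ended without WT M0 replicate 1 or 3, KO M0 replicate 6, 7 or 8, WT IL4 replicate 1, 3 or 4, or KO IL4 replicate 7 or 8 (0.0535 to 0.0951).

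For the other contrasts 1 of 35 splits, the real one, called as many genes, a share of 0.0286. This is the smallest share that 35 splits can give, and it holds only for libraries taken as independent. It sets the real split apart from the others but does not exclude chance. Numbers pair the KO M0 and IL-4 libraries, so for IL-4 against M0 in KO these free splits are no null. If the libraries of a number pair share an animal, which the labels do not say, the splits are no null for any of the other contrasts. With number pairs summed, KO against WT called 285 higher and 272 lower in M0. KO against WT called 3279 genes in M0, where the highest other split called 1, and 5307 in IL-4, where it also called 1. In LPS the real count was 4534 and the highest other 4077. That split exchanged WT LPS replicate 2 and KO LPS replicate 7, both shallow. LPS against M0 called 8472 genes in WT (highest other 3589) and 9885 in KO (5785). Each of these other splits exchanged 1 shallow LPS library with 1 M0 library. IL-4 against M0 called 8836 genes in WT (highest other 1) and 7534 in KO (383). The split with 383 genes set KO numbers 5 and 6 against 7 and 8 and parted no pair of equal numbers, while the real split parts all 4 pairs. The next split called 8, and it parted 2 pairs.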

How the results depend on the processing

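The tests without the 3 shallow libraries, without KO numbers 5 and 6 or 7 and 8, and with number pairs summed were chosen only after the results were seen. No result reversed its direction while called in any setting, and the cause of the changes was not tested. Counts are given as higher and lower where they moved by over 1.5 times. DESeq2 called 767 and 671 genes for KO against WT in M0, 1046 lower in LPS, 1482 and 1309 in IL-4, 2949 higher for IL-4 against M0 in WT and 2145 higher in KO. For the interactions it called 643 and 215 genes with LPS and 35 and 47 with IL-4. DESeq2 gave no adjusted p for 21 named genes, which were left out of its comparison. A fit on only the groups compared called 135 and 165 genes in the IL-4 interaction. With the replicate number as a block, 1620 and 1367 genes were called in the LPS interaction and 497 and 621 in the IL-4 interaction.

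With number pairs summed (15577 genes tested), KO against WT called 285 and 272 genes in M0, 1142 and 946 in LPS and 934 and 896 in IL-4, and IL-4 against M0 in KO called 2139 lower. The LPS interaction then called 58 and 7 genes (2223 at an unadjusted p under 0.05). The IL-4 interaction called 0 and 0 by edgeR (795 at an unadjusted p under 0.05), where DESeq2 on all libraries called 35 and 47. Without KO numbers 5 and 6, 2564 genes were lower in KO M0 and the IL-4 interaction called 381 and 296. Without KO numbers 7 and 8, the LPS interaction called 1548 higher and the IL-4 interaction 39 lower. Without the 3 shallow libraries every count of the LPS contrasts stayed within 1.5 times.

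Leaving out 1 library at a time gave 1113 to 1557 higher and 1299 to 1782 lower for KO against WT in M0 (1738 and 1541 with all libraries). In LPS it gave 1724 to 2604 higher and 1275 to 2144 lower (2384 and 2150), and in IL-4 2082 to 2487 and 2334 to 2740 (2632 and 2675). The LPS interaction gave 717 to 1362 higher and 225 to 971 lower (972 and 704), and the IL-4 interaction 27 to 148 and 33 to 212 (69 and 98). The lowest values came without KO M0 replicate 7 (1113), WT LPS replicate 4 (1275), WT LPS replicate 3 (225) and WT M0 replicate 3 (27 and 33), with 27 higher also without WT IL4 replicate 2. The highest IL-4 interaction counts came without WT M0 replicate 2.

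Gene lists called by camera with an estimated correlation numbered 0 for KO against WT in M0 (6 at an unadjusted p under 0.05, with 2 by fry) and 0 in LPS (0 at an unadjusted p under 0.05, with 11 by fry). They numbered 2 in IL-4, 5 for LPS against M0 in WT, 4 for IL-4 against M0 in WT, 6 for LPS against M0 in KO and 4 for IL-4 against M0 in KO. For the interactions they numbered 0 with LPS (3 at an unadjusted p under 0.05, with 3 by fry) and 2 with IL-4. Fry called 5 in IL-4, 17 for LPS against M0 in KO and 0 for the IL-4 interaction (3 at an unadjusted p under 0.05). Camera with a preset correlation called 15 there. Without KO numbers 7 and 8, camera called 15 lists in LPS. Without KO numbers 5 and 6 it called 17 in IL-4 and 7 for the LPS interaction.

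For the named genes, calls that ended and calls that were gained numbered 5 and 1 in DESeq2, 1 and 2 with RLE factors, 2 and 1 without a filter, and 3 and 0 with only the groups compared. They numbered 0 and 2 with the replicate block, 37 and 0 with number pairs summed, 4 and 2 without KO numbers 5 and 6, 8 and 1 without KO numbers 7 and 8, and 1 and 0 without the shallow libraries. Over all fits that left out 1 library they numbered 103 and 9, against 1656 with the same call. With RLE in place of TMM factors the median log2 fold change of all genes moved from -0.0145 to -0.113 for LPS against M0 in WT and from -0.0668 to -0.153 in KO.

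Correlations of deviations between equal numbers in the other groups ranged from -0.074 to 0.099 for WT M0 and LPS, -0.15 to 0.7 for WT M0 and IL-4, and -0.046 to 0.096 for WT LPS and IL-4. In KO they ranged from 0.049 to 0.13 for M0 and LPS and from 0.014 to 0.15 for LPS and IL-4. Over the limit of 0.1 lay 3 of 4 pairs in each of these KO comparisons and 2 of 4 for WT M0 and IL-4. By the rule used, which asks for 4 of 4, the numbers did not pair these libraries. That does not show them to be unpaired, since 3 LPS libraries are shallow and Ifi202b recurred by number in each state.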

Other observations

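The tests on label numbers, stromal markers, Lyz2 and the segment beside Ogt were chosen only after the results were seen. Within KO, several gene lists differed by label number. By the F test on the number, 20 of 24 cholesterol biosynthesis genes were called within KO and 0 within WT, as were 21 and 3 of 44 interferon-stimulated genes, 13 and 4 of 28 M1 markers, 14 and 2 of 32 IL-4 markers and 7 and 0 of 8 endothelial markers. Between KO numbers 7 and 5, adjusted for state, Nell2 differed by 2.39 and Mest by 2.07 on the log2 scale, and Cd74, the MHC class II chaperone, by -1.02. Numbers 8 and 5 differed by 2.30, 1.74 and -1.15 in the same genes. Numbers 6 and 5 differed by -0.33, 0.17 and -0.083.

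Saa3, Il1b and Marco were higher in WT M0 replicate 1 than in the other unstimulated WT libraries. Saa3 stood at 69.3 CPM against 8.22, 4.56 and 7.86 CPM, Il1b at 4.003 CPM against 0.941, 0.587 and 0.680 CPM, and Marco at 7.98 CPM against 1.86, 1.60 and 0.969 CPM. These 3 genes were chosen because they differ, and no test was made. Shallow and deep libraries were alike in their summary lines. Reads outside genes made up 3.11 to 3.59% of all reads listed in deep and 3.14 to 3.47% in shallow libraries, and reads with several alignments 3.60 to 4.50% and 3.96 to 4.30%.

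KO libraries differed by label number (2271 genes called within KO, 207 within WT). A different share of 1 stromal cell type is argued against, since 8 abundant stromal markers moved apart between KO numbers 7 and 5, from Cxcl12 (-0.51 ± 0.10) to Postn (1.01 ± 0.079), with a heterogeneity chi-square of 209 on 7 degrees of freedom. A different level of interferon among the KO cultures may explain part of the pattern, since of 19 interferon-stimulated genes of the fixed list with a number effect outside chromosome 1 from 170 to 180 Mb, 19 were lower in KO number 7 than in 5 and 0 higher (from -0.28 for Irf1 to -1.35 for Oas3), although Ifi202b, which interferon induces, was higher by 9.53. A chromosome segment from another strain in some KO cultures alone is argued against by 0 windows of 10 Mb crowded in KO and not in WT, while a segment from another strain that differs between cultures of both genotypes is a candidate explanation for the 1 window crowded in both (chromosome 1, 170 to 180 Mb, 42 genes), a form of the test added after the WT windows were seen. These 42 and 19 genes are a small part of the 2271, so the cause of the rest stays open, and differences between animals, cultures or days of work were not tested because the labels do not give them.

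Stromal markers were higher in KO, with Col1a1 at 8442 CPM in KO M0 and 5342 CPM in WT M0, Col1a2 at 5614 and 3759 CPM and Col3a1 at 2061 and 1443 CPM, so WT cultures hold these transcripts as well, and all 10 genes of the list passed the count filter. A higher share of 1 stromal cell type would move 8 abundant markers by 1 factor. They did not share 1 in M0 (chi-square 77.8 on 7 degrees of freedom, from Pdgfra at -0.22 to Postn at 0.73), LPS (63.5) or IL-4 (64.2). They also moved apart between KO numbers 7 and 5, so label number may give this spread and the test does not decide. A lower share of macrophages alone would raise markers of all other cell types by 1 factor. The 22 such markers did not share 1 factor, from Mmp8 (-0.76) to Egfl7 (2.01) in M0 (chi-square 368), with 273 in LPS and 282 in IL-4. Any single cell type that varies, or the label number, would give such a spread, so the test does not decide this either. Both stay open, as do a change within the stromal cells, several such cell types and expression by macrophages, which were not tested. The labels name no sort that would remove stromal cells.

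Lyz2 was lower in KO in all 3 states, by -0.87, -1.17 and -0.46. Loss of 1 of 2 Lyz2 copies alone is argued against, since the IL-4 value lies 7.53 SE from -1, while M0 (1.77 SE) and LPS (2.23 SE) lie nearer. A count of Lyz2 reads for the neighbouring paralog Lyz1 instead is argued against, since Lyz1 would then gain them, and it was called lower in all 3 states (-0.84, -0.92 and -0.29). Other sharing of reads, by which the genes would fall together, a copy loss with regulation of the other copy, and lower expression of both genes stay open, and no biological explanation was tested.

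A passenger chromosome segment beside the targeted gene would crowd the genes called in the same direction in all 3 states around Ogt. The lowest adjusted p over 259 windows of 10 Mb was 1, and from 100 to 110 Mb on chromosome X 2 of 54 genes were such genes, against 4.52 by the genome-wide share. From 90 to 100 Mb 3 of 29 were, against 2.43.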
